A study of Mus musculus with 40 samples.

How the data were processed

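Faecal samples of 40 wild-type mice were labelled as young, old, young cohoused or old cohoused, 10 samples per group. DNA was purified with the DNeasy PowerSoil Pro kit, amplified with KAPA HiFi over the V1V2 region of the 16S gene (primers F27 and R338) and sequenced as paired ends on an Illumina MiSeq, per the labels' protocols. The deposited table holds read counts per sequence feature, made from a biom file per the file headers, with 3518 features and 99 columns. The tool that produced the features, its filters and its chimera removal are not given in the sources used here, and each feature has at least 10 reads over all columns. The deposited taxonomy gives each feature a name from domain to species and a confidence as a fraction, from 0.7003 to 1 with a median of 0.9879. The classifier and its reference are not given in the sources used here. A genus was named for 2168 features and a species for 308, so species names cover a small part of the table. Features are called ASVs here, numbered by their reads in the 40 libraries.

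The columns carry numbers as names, and the labels give library names that also end in a number. Columns 1 to 40 were given to the samples whose library name holds the same number. This was decided on names before the values were tested, rests on the number alone and was kept after the group tests. If the numbers of the table are not those of the library names, every group comparison is void. Composition and the relation between columns would then still hold for the columns used, but these need not be the labelled mice. The other 59 columns were not used here. The series description speaks of transplants with inputs, the title of cohousing, and the sample labels were followed.

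Features named as mitochondria, chloroplast or eukaryote or without a domain were left out, which removed 1 feature with 0 reads in the columns used. No library had fewer than 1000 reads, and 0 pairs of libraries were identical. The columns used hold 3326 ASVs and 116 genus-level taxa, where features without a genus were summed at the deepest named rank. Taxa with at least 10 reads in at least 5 libraries were tested: 1066 ASVs with 96.2% of reads and 99 genera with 99.96% of reads, 86 of them with a genus name. Library totals of 44298 to 135690 reads give 95% Wilson intervals of at most 0.418 percentage points to either side of a share, and 0 reads of a taxon allow up to 0.00221% to 0.00677%. These intervals cover counting error only, because PCR copies of a molecule are counted as separate reads.

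Counts were fitted with edgeR 4.0.16 (R 4.3.3), quasi-likelihood with robust spread and TMMwsp scaling, with all 4 groups in 1 fit and Benjamini-Hochberg adjustment at 0.05. Contrasts were old against young, cohoused young against young, cohoused old against old, cohoused old against cohoused young, and the interaction of age and cohousing. Fitted folds are log2. Shannon diversity and the number of ASVs were computed after rarefaction to 44298 reads, as the mean of 100 draws. Diversity, distances, phyla, taxon lists and fixed taxa were compared with 2-sided permutation tests of the difference in means, with 100000 resamples, or all arrangements where a group had fewer than 10 libraries. They were adjusted by Benjamini-Hochberg within a measure, over the phyla, over the lists or over the fixed taxa of a comparison. The fixed taxa were adjusted as 8 values, because Parabacteroides and Parabacteroides goldsteinii were entered separately and held the same reads. Bray-Curtis dissimilarity of ASV shares was tested with PERMANOVA in vegan 2.7.1 with 99999 permutations, adjusted over the 6 pairs of groups, and the spread of groups with 9999 permutations. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for the permutation tests. The edgeR fit was tested on simulated counts for old against young: among 99 genera it called 3 of 69 unchanged ones, and among 1066 ASVs it recovered 3 of 67 changed 4-fold, 20 of 67 changed 16-fold and 45 of 66 changed 64-fold and called 17 of 866 unchanged ones.

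The tests, contrasts, filters, taxon lists, fixed taxa and most alternatives were chosen before the data were examined. Taxa to be named were genera past the threshold with medians or prevalences in the direction of the fit (at most 10 each way), ASVs past it with at least 0.1% of reads in 1 group (at most 5 each way), passing members of the lists, and the fixed taxa whatever their result: Parabacteroides with Parabacteroides goldsteinii, Bacteroides, Alistipes, Muribaculaceae, Akkermansia, Lactobacillus, Bifidobacterium and Turicibacter. The 11 lists were Bacteroidales fermenters, Tannerellaceae, butyrate producers, lactic acid bacteria, mucin users, sulfidogenic bacteria, proteobacterial opportunists, Erysipelotrichales, segmented filamentous bacteria, Mollicutes with Gastranaerophilales, and reagent and skin genera. Their genera were also tested over the list alone.

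Alternatives were TMM, total-read and DESeq2 poscounts scaling in edgeR; DESeq2 1.42.0 (Wald test); limma 3.58.1 on centred log-ratios with a pseudocount of 0.5; no filter on low counts, and 10 reads in 10 libraries; the replicate number as a block; and a fit of the compared groups alone. For diversity they were no rarefaction and filtered ASVs, for distances Jaccard, Aitchison and genus level, and for shares log10 of the percent plus 0.01. Added after the data were seen were leaving out libraries far from the rest, blocks of 8 consecutive library numbers, and the log10 scale for the fixed taxa. A library counted as far where its median dissimilarity to the others exceeded the median of all libraries, 0.527, by 3 median absolute deviations, which is 0.743.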

Results

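Faecal bacteria of wild-type mice were profiled by sequencing the V1V2 region of the 16S rRNA gene, a marker whose variable stretches separate bacterial taxa. The labels name 4 groups of 10 samples each: young mice, old mice, young mice cohoused and old mice cohoused. Mice that share a cage exchange faecal bacteria, so cohousing lets the communities of young and old animals mix. The 40 libraries held 3898503 reads in all, from 44298 to 135690 per library with a median of 96330.5. Mean totals were 105317 ± 16215 reads (SD, n = 10) for the young group and 98146 ± 18224 for the old group. Cohoused young libraries held 94699 ± 19755 reads and cohoused old libraries 91688 ± 21168. The count table names its columns by number only, and each column was matched to the sample whose library name carries the same number. This match rests on the number alone, so a group below means the libraries matched by number to mice with that label. Every group comparison is only as good as that match, and so is the reading of the 40 columns as these mice. The labels name neither cages nor litters, and cage-mates share bacteria, so the libraries may not be independent and p-values may be too small.

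Firmicutes took 57.0% ± 10.8 (SD, n = 40) of the reads and Bacteroidota 39.8% ± 11.1, followed by Proteobacteria with 2.15% ± 1.34. Muribaculaceae, fermenters of plant and host glycans that are typical of the mouse gut, were the most abundant family at 26.2% ± 8.58. Lachnospiraceae, a family with many butyrate makers, held 19.7% ± 11.9 and Lactobacillus, a genus of lactic acid bacteria, 18.4% ± 9.52. Prevotellaceae held 5.68% ± 4.44, all of it in the feature with the most reads, called ASV1. Parabacteroides goldsteinii accounted for every Parabacteroides read and was found in all 40 libraries, at a median of 0.0515%. Akkermansia, which grows on intestinal mucin, was found in 14 of the 40 libraries at a mean of 0.00173%, and no feature carried the name Bifidobacterium or Helicobacter. How well the primers amplify these genera was not tested, so low or missing reads do not show that the mice lacked them.

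The 40 communities did not separate by labelled group. Group membership accounted for 4.52% of the variation in Bray-Curtis dissimilarity, below the 12.4% that 95 of 100 random relabellings stayed under (PERMANOVA, permutation p = 0.940). The mean dissimilarity was 0.628 within groups and 0.611 between groups. Instead, 5 libraries with consecutive numbers, 34 to 38, stood far from the rest. They carry all 4 labels: old 9, cohoused old 9, young 9, cohoused old 10 and cohoused young 10. Turicibacter made up 9.36% to 17.1% of their reads, Parabacteroides goldsteinii 0.754% to 4.47%, and Bacteroides no more than 0.00490%. Parabacteroides goldsteinii reached at most 0.144% in the other 35 libraries.

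**Figure D1:**
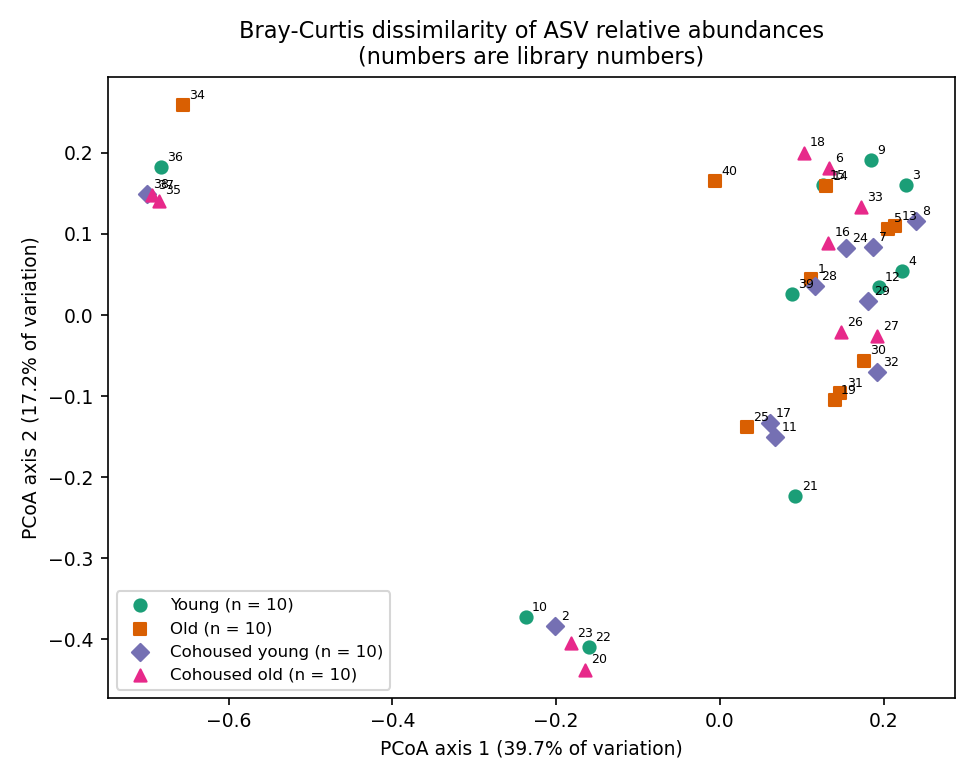
Principal coordinates of the Bray-Curtis dissimilarity between the 40 libraries, with axis 1 (39.7% of variation) against axis 2 (17.2%). Each point is 1 library, colour and shape give the labelled group (n = 10 each) and the small number is the library number; libraries 34 to 38 lie together on the left and carry all 4 labels.

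Libraries with consecutive numbers resembled each other, at a mean dissimilarity of 0.494 over 39 pairs against 0.615 in random orders (1-sided permutation p = 1e-05, the smallest these permutations can give). Without libraries 34 to 38, where 33 and 39 became neighbours in the order, the values were 0.493 and 0.533 (p = 0.0106). Much of the gap thus comes from these 5, and this comparison was chosen after the data were seen. Only 8 of the 39 pairs share a label, where random labels would give 9.01, so labels as matched by number do not explain the likeness.

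**Figure D2:**
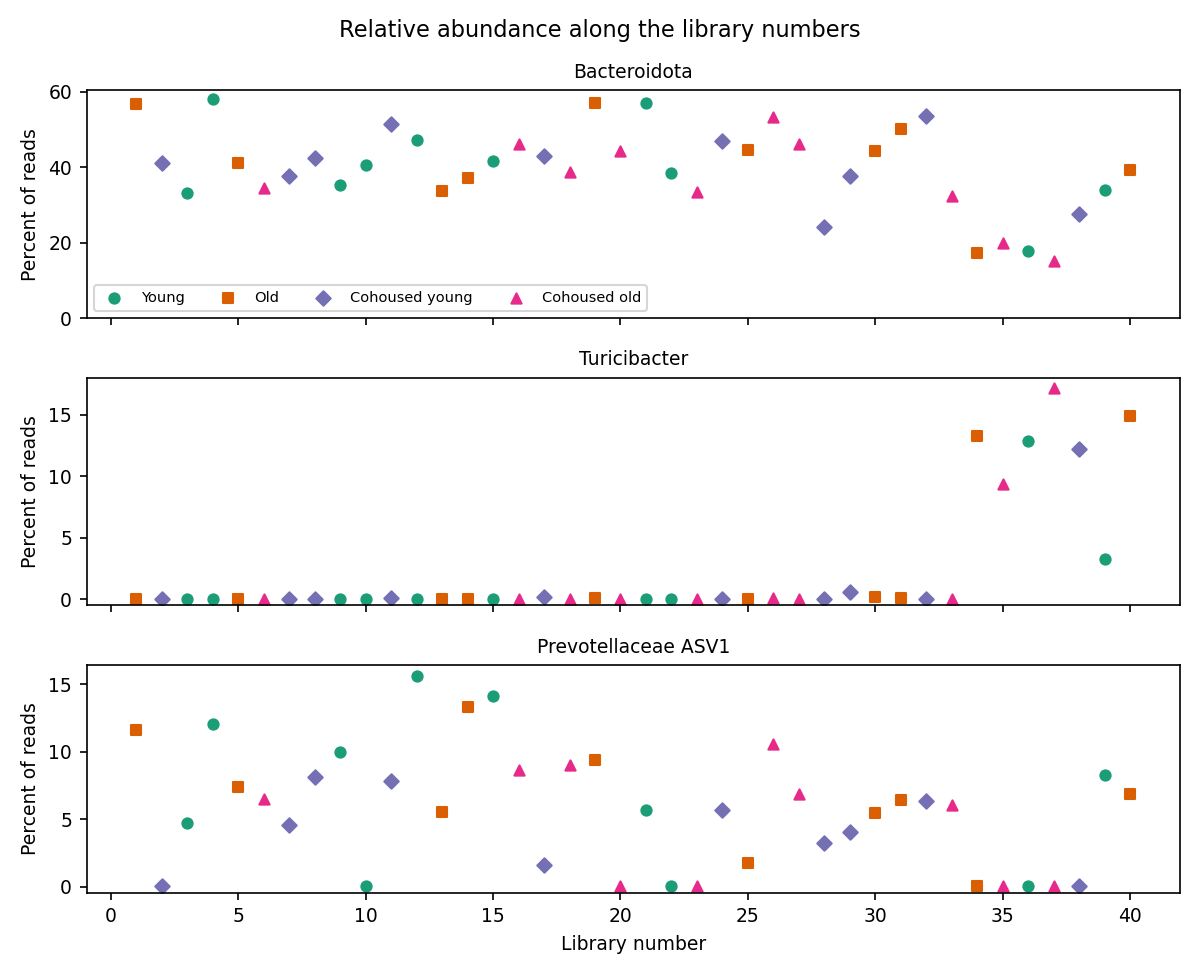
Percent of reads per library (vertical axis) along the library number (horizontal axis) for Bacteroidota, Turicibacter and ASV1 of Prevotellaceae, with colour and shape giving the labelled group (n = 10 each). Turicibacter exceeds 3% only in libraries numbered 34 to 40, and libraries 34 to 38 hold the lowest shares of Bacteroidota together with library 28.

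The first comparison asks how faecal bacteria differ between separately kept old and young mice. The mean shares of the major taxa lay at similar levels in both groups. Muribaculaceae held 27.4% ± 9.54 (SD, n = 10) of reads in old and 25.1% ± 10.0 in young libraries, with medians farther apart, at 27.7% and 19.7%. Lactobacillus held 18.2% ± 10.1 in old and 18.7% ± 10.4 in young libraries. Bacteroides, which breaks down polysaccharides, stood at 2.56% ± 1.61 in old and 3.11% ± 1.90 in young libraries, and Alistipes at 2.48% ± 1.37 and 2.68% ± 2.23. Parabacteroides goldsteinii averaged 0.492% ± 1.40 in old and 0.128% ± 0.224 in young libraries, and Turicibacter 2.86% ± 5.95 and 1.62% ± 4.09. These means rest on few libraries: without numbers 34 to 38 the old-minus-young difference of Parabacteroides goldsteinii turned to -0.00769 percentage points. Akkermansia was detected in 5 of 10 old and 2 of 10 young libraries, at means of 0.00237% and 0.000906%. None of these 7 taxa passed the permutation test (2-sided, 100000 resamples, Benjamini-Hochberg adjusted p = 0.906 for each).

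Erysipelotrichales, an order with several bile-tolerant mouse commensals, held 4.53% ± 6.97 of reads in old and 9.33% ± 8.82 in young libraries. Among its members Dubosiella averaged 0.893% ± 1.68 in old and 4.23% ± 4.87 in young libraries, and Faecalibaculum 0.583% ± 0.754 and 3.22% ± 4.02. Their fitted log2 fold changes, -2.93 ± 1.57 (SE) and -2.68 ± 1.41, did not pass edgeR's quasi-likelihood test (adjusted p = 0.948 for both). The Dubosiella means rest on few libraries, with 5.11% in old library 40 and 15.1% and 8.25% in young libraries 10 and 22. Bacteroidales fermenters held 34.6% ± 9.85 in old and 32.8% ± 10.6 in young libraries, butyrate producers 8.99% ± 5.75 and 7.45% ± 5.70, and lactic acid bacteria 18.2% ± 10.0 and 18.8% ± 10.4. Proteobacterial opportunists, nearly all Parasutterella, held 1.54% ± 1.06 in old and 1.84% ± 1.14 in young libraries. That share describes Parasutterella and says little about opportunists in general. Mucin users stood at 0.460% ± 0.428 and 0.620% ± 0.588, and segmented filamentous bacteria, which attach to the ileal epithelium, at 0.310% ± 0.340 and 0.453% ± 0.760. Over the 40 libraries mucin users averaged 0.463%, of which Mucispirillum alone held 0.439%. Mollicutes with Gastranaerophilales stood at 0.166% ± 0.120 in old and 0.177% ± 0.138 in young libraries, and sulfidogenic Desulfovibrionales at 0.0684% ± 0.0586 and 0.0399% ± 0.0475. Reagent and skin genera, here only Staphylococcus, stood at 0.0398% ± 0.123 and 0.00717% ± 0.0134. The old mean comes almost wholly from library 40, with 0.390%, where the other old libraries held at most 0.00400%. The Tannerellaceae list held Parabacteroides alone, and that list was drawn up with this genus in mind, so it is not independent evidence. None of the 11 list shares passed (adjusted p = 0.913 for each), and 0 of the 34 listed genera passed over all genera or adjusted over the list alone.

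Among 99 genera tested with edgeR, 0 passed at an adjusted p of 0.05 and 1 had an unadjusted p under 0.05. That genus, named Incertae Sedis in the taxonomy, averaged 0.450% ± 0.408 in old and 0.200% ± 0.146 in young libraries (log2 fold change 1.21 ± 0.42, edgeR adjusted p = 0.657). limma on centred log-ratios called 0 genera and DESeq2 called 1, Romboutsia, with a log2 fold change of 5.27 against 1.47 in edgeR. Few libraries carry this genus: its highest shares were 7.49% and 4.62% in old libraries 34 and 40 and 2.50% and 2.39% in young libraries 36 and 39. Among 1066 ASVs, 2 passed in edgeR, 113 had an unadjusted p under 0.05, DESeq2 called 14 including both of these, and limma called 0. They lie below the abundance of 0.1% set for named ASVs and are named here after their values were seen. ASV410, an Oscillibacter, had 515 reads in old and 0 in young libraries, and was found in 7 of 10 old libraries, with 236 reads in library 5. ASV659, an unclassified member of Oscillospiraceae, had 217 reads in old and 0 in young libraries, and was also found in 7 of 10 old libraries, with 96 reads in library 14. With 3 reads over the group as the limit for 0 reads, the pooled shares of ASV410 and ASV659 were at least 184-fold and 77.6-fold higher in old libraries. These limits cover counting error only and leave out the spread between libraries. The log2 fold changes in edgeR were 8.15 ± 1.85 (SE) and 6.98 ± 1.58 (edgeR adjusted p = 0.0440 for both). Without library 5 the first limit is 112-fold, and without library 14 the other is 49.2-fold. Neither passed under the other 3 scalings in edgeR, where the adjusted p values were 0.0578 to 0.0628, nor in the fit of these groups alone, at 0.0521 for both, nor without libraries 34 to 38, at 0.0694 for both, where the fitted log2 fold changes were 8.48 and 7.31 against 8.15 and 6.98 with all libraries. With the replicate number as a block 0 ASVs passed (lowest edgeR adjusted p = 0.109). In a simulation of this comparison edgeR recovered 4 of 10 genera changed 4-fold, 9 of 10 changed 16-fold and 10 of 10 changed 64-fold. For ASVs it recovered 3 of 67, 20 of 67 and 45 of 66 at the same folds. It also called 3 of 69 unchanged genera and 17 of 866 unchanged ASVs. Calls near an adjusted p of 0.05 may thus hold more false ones than that threshold allows.

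Old libraries held 947 ± 198 ASVs at a depth of 44298 reads and young libraries 774 ± 213, a difference of 172.9 ± 91.9 (SE; permutation p = 0.0785, adjusted p = 0.314). Shannon diversity was 4.60 ± 0.643 in old and 4.33 ± 0.627 in young libraries (adjusted p = 0.646). Age group accounted for 3.32% of the variation in Bray-Curtis dissimilarity (PERMANOVA p = 0.736, adjusted p = 0.948), against 9.84% at the 95th percentile of random relabellings. The spread around the group centres did not differ detectably (permutation p = 0.472).

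**Figure D3:**
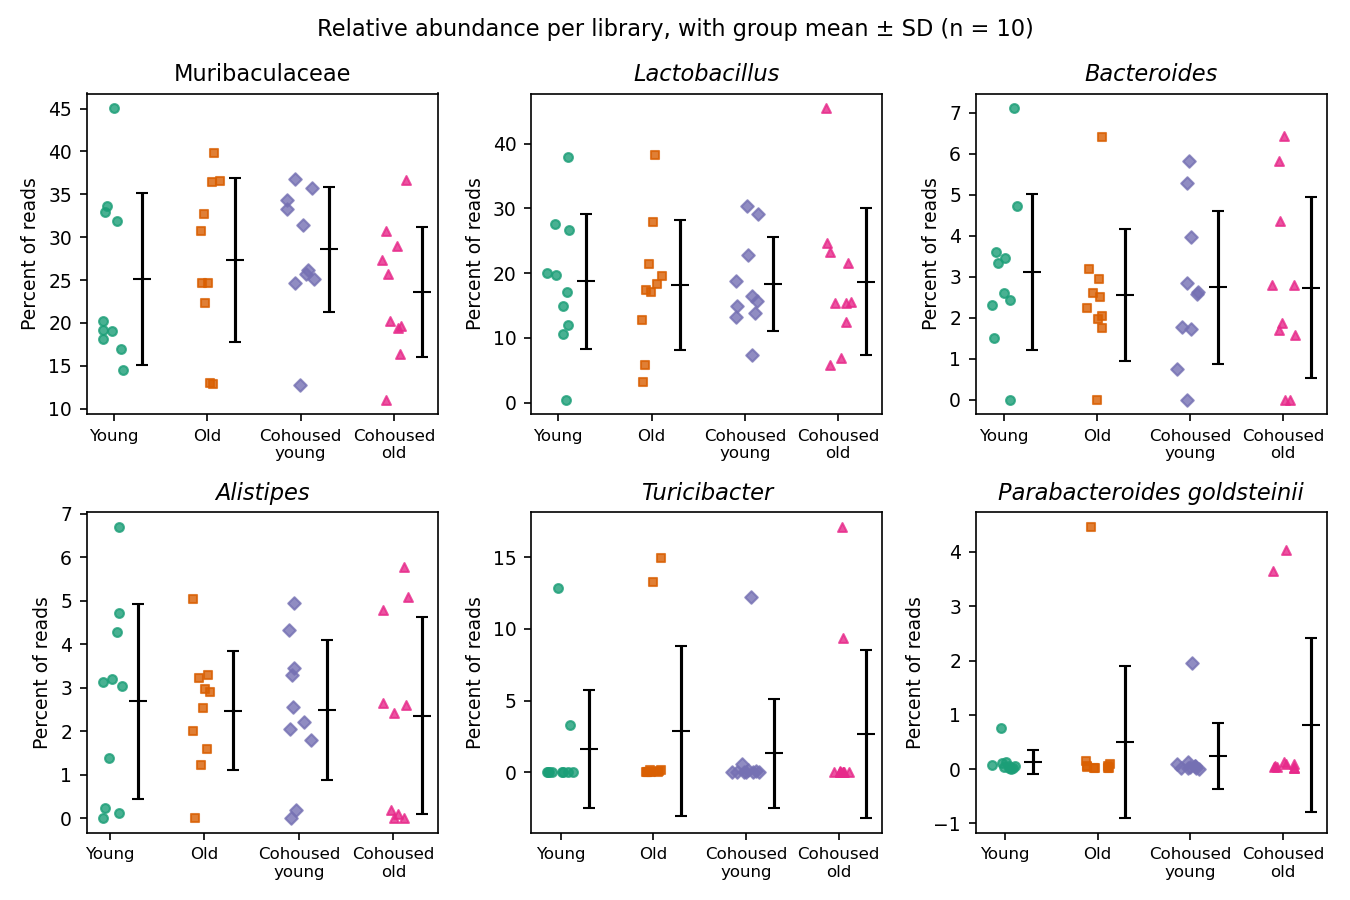
Percent of reads per library for 6 taxa fixed in advance, by labelled group on the horizontal axis (n = 10 each); points are libraries and the bars beside them give the mean and 1 SD. The groups overlap in every panel, and the high values of Turicibacter and Parabacteroides goldsteinii come from few libraries, which carry all 4 labels.

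The next comparison asks what cohousing changed in young mice. In the taxa fixed in advance, cohoused young libraries did not differ detectably from young libraries. Muribaculaceae held 28.6% ± 7.26 (SD, n = 10) in cohoused young libraries, 3.47 percentage points above the young group, with medians of 28.8% and 19.7%. Lactobacillus held 18.3% ± 7.25. Bacteroides stood at 2.74% ± 1.86, Alistipes at 2.48% ± 1.61, Turicibacter at 1.30% ± 3.83 and Parabacteroides goldsteinii at 0.241% ± 0.604. Without libraries 34 to 38 the cohoused-minus-separate difference of Parabacteroides goldsteinii turned from 0.113 to -0.00788 percentage points. Akkermansia was detected in 5 of 10 cohoused young libraries at a mean of 0.00313%. None of the 7 taxa passed against the young group (permutation test, adjusted p = 0.919 for each).

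Of the 11 lists, 0 differed in share (permutation test, adjusted p = 0.935 for each). Erysipelotrichales held 6.14% ± 8.11 of reads in cohoused young libraries, and all 5 of its tested genera had fitted folds below 0 without passing. Of 9 butyrate producers tested, 6 had fitted folds above 0 and 3 below. Roseburia, a butyrate producer, averaged 1.15% ± 1.24 against 0.509% ± 0.390 in young libraries (log2 fold change 1.05 ± 0.51, edgeR adjusted p = 0.997, and 0.360 adjusted over the list alone). edgeR called 0 of 99 genera, 1 with an unadjusted p under 0.05, and 0 of 1066 ASVs, 85 with an unadjusted p under 0.05. DESeq2 called 0 genera and 6 ASVs, and limma 0 of either. Cohoused young libraries held 900 ± 217 ASVs, 125.3 ± 96.1 (SE) more than young libraries (permutation test, adjusted p = 0.420), and had a Shannon diversity of 4.62 ± 0.699 (adjusted p = 0.646). Housing accounted for 2.08% of the variation between these groups (PERMANOVA p = 0.948, also after adjustment).

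For old mice, the same question set cohoused against separately kept animals. Muribaculaceae held 23.6% ± 7.63 (SD, n = 10) of reads in cohoused old libraries, 27.4% in old ones, and Lactobacillus 18.6% ± 11.4. Bacteroides stood at 2.74% ± 2.21, Alistipes at 2.36% ± 2.26, Turicibacter at 2.66% ± 5.87 and Parabacteroides goldsteinii at 0.813% ± 1.60. The latter means rest on libraries 35 and 37, with 9.36% and 17.1% Turicibacter and 3.64% and 4.03% Parabacteroides goldsteinii. Without libraries 34 to 38 the difference from old libraries went from -0.195 to -1.68 percentage points for Turicibacter and from 0.321 to 0.00703 for Parabacteroides goldsteinii. The Turicibacter value then rests on old library 40, with 14.9%. Akkermansia was detected in 2 of 10 cohoused old libraries at a mean of 0.000518%. None of the 7 taxa passed (permutation test, adjusted p from 0.442 to 0.920). Firmicutes made up 60.7% ± 11.1 of cohoused old and 54.8% ± 11.4 of old libraries, and Bacteroidota 36.4% ± 11.98 and 42.1% ± 11.7, without passing (permutation test, adjusted p = 0.600 for both).

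None of the 11 list shares passed between cohoused old and old libraries (permutation test, adjusted p = 0.954 for each). Erysipelotrichales held 9.98% ± 11.99 of reads in cohoused old libraries. Dubosiella averaged 4.90% ± 6.55 there, with 16.7% and 16.1% in libraries 35 and 37 (log2 fold change against old 3.57 ± 1.62) and Faecalibaculum 2.15% ± 2.73 (3.10 ± 1.43), both with an edgeR adjusted p of 0.900, and 0 of 5 members passed over all genera or adjusted over the list alone. Anaeroplasma, a cell-wall-less member of the Mollicutes, was found in 5 of 10 old and 1 of 10 cohoused old libraries, at 0.0101% ± 0.0145 and 0.000202% ± 0.000639. Its fitted log2 fold change of -5.08 ± 1.71 did not pass over all genera (edgeR adjusted p = 0.510) but passed adjusted over the list alone, of 3 genera (adjusted p = 0.0154). Over that list it did not pass in DESeq2 (log2 fold change -5.18, adjusted p = 0.118), in limma (-1.67, 0.374) or in edgeR without libraries 34 to 38 (-4.36, 0.0712). Nor did it pass over the list in edgeR with the replicate number as a block (-3.30, 0.200). edgeR called 0 of 99 genera, 4 with an unadjusted p under 0.05, and 0 of 1066 ASVs, 85 with an unadjusted p under 0.05. DESeq2 called 1 genus, Turicibacter, with a log2 fold change of -6.00 and 6 ASVs, and limma called 0 of either. For Turicibacter edgeR gave -0.06 with all libraries and -6.61 without libraries 34 to 38, neither passing. Of the old libraries left in the latter fit, library 40 held 14.9% Turicibacter and library 30, the next highest, 0.151%. A fit of these 20 libraries alone called 15 ASVs, all higher in cohoused old libraries. Cohoused old libraries held 835 ± 290 ASVs (permutation test, adjusted p = 0.431 against old) and had a Shannon diversity of 4.45 ± 0.785 (adjusted p = 0.646). Housing accounted for 4.70% of the variation (PERMANOVA p = 0.416, adjusted p = 0.948).

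Within the cohoused animals, old and young mice were compared to ask which age difference remained. Muribaculaceae differed by -4.99 percentage points in cohoused old against cohoused young libraries (-2.83 without libraries 34 to 38), and Lactobacillus by 0.357 points, a difference that turned to -0.0775 points without libraries 34 to 38. Parabacteroides goldsteinii lay 0.572 ± 0.540 (SE) points higher and Turicibacter 1.36 points higher in cohoused old libraries. Without libraries 34 to 38 the Parabacteroides goldsteinii difference was 0.00722 points and the Turicibacter difference turned to -0.0766 points. Bacteroides and Alistipes differed by -0.00436 and -0.120 points, and without libraries 34 to 38 by 0.375 and 0.194 points. Akkermansia, at 0.000518% in cohoused old and 0.00313% in cohoused young libraries, did not pass either, and adjusted p values of the 7 taxa ran from 0.608 to 0.993 (permutation test, n = 10 per group). Anaeroplasma was found in 2 of 10 cohoused young libraries, at 0.0115% ± 0.0292, and 1 of 10 cohoused old libraries. Its log2 fold change of -5.14 ± 1.71 passed adjusted over the list alone (edgeR adjusted p = 0.0141) and not over all genera (0.465). Over that list it did not pass in DESeq2 (log2 fold change -5.11, adjusted p = 0.126) or in limma (-0.79, 0.696). Nor did it pass over the list in edgeR with the replicate number as a block (-2.55, 0.498).

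None of the 11 list shares differed between the cohoused groups (permutation test, adjusted p = 0.959 for each). All 5 Erysipelotrichales genera tested had fitted folds above 0, and 7 of 9 butyrate producers had fitted folds below 0, with none passing. The summed share of butyrate producers was nevertheless not lower, at 9.16% ± 6.53 in cohoused old and 8.74% ± 6.20 in cohoused young libraries. edgeR called 0 of 99 genera, 1 with an unadjusted p under 0.05, and 0 of 1066 ASVs, 29 with an unadjusted p under 0.05. DESeq2 called 0 genera and 4 ASVs, and limma 0 of either. Richness differed by -64.2 ± 114.4 ASVs (SE; permutation test, adjusted p = 0.578). Age group accounted for 2.74% of the variation between the cohoused groups (PERMANOVA p = 0.819, adjusted p = 0.948).

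Whether the age difference itself differed between housing conditions was tested with the interaction of age and cohousing. edgeR called 0 of 99 genera, 4 with an unadjusted p under 0.05 (Anaeroplasma, Coriobacteriaceae UCG-003, Allisonella and Faecalibaculum), where DESeq2 called 1, Romboutsia, and limma 0. At ASV level edgeR called 7 of 1066, 111 had an unadjusted p under 0.05, DESeq2 called 9 of which 2 were shared, and limma called 0. These 7 are named here after their values were seen. ASV278, of the Eubacterium xylanophilum group, a butyrate-producing lineage, had 661 reads in young, 0 in old, 35 in cohoused young and 867 in cohoused old libraries. ASV288, of Clostridia UCG-014, had 514, 2, 57 and 944 reads in the same order, and its direction turned in DESeq2 (interaction log2 fold change -1.88). ASV397 and ASV514, both Ruminococcus, a genus with fibre-degrading members, had 457 and 431 reads in young against 5 and 5 in old libraries, and 33 and 8 in cohoused young against 384 and 143 in cohoused old libraries. ASV622 (Tyzzerella), ASV856 (Clostridium sensu stricto) and ASV979 (Eubacterium siraeum group) went the other way, with 0 reads in young and 164, 183 and 68 in old libraries. Cohoused young libraries held 258, 55 and 127 reads of these 3, and cohoused old libraries 29, 23 and 8. Few libraries carry these reads: the young reads of ASV278, ASV288, ASV397 and ASV514 come from 2 of 10 libraries each, with 534, 495, 366 and 353 in libraries 22, 36, 15 and 39. Of the cohoused old reads, 551 of ASV278 were in library 20, all 944 of ASV288 and 349 of ASV397 in library 37, and 74 of ASV514 in library 27. For ASV622, ASV856 and ASV979, the highest libraries held 80, 72 and 46 of the old reads (libraries 14, 31 and 31) and 255, 32 and 95 of the cohoused young reads (libraries 17, 32 and 28). Adjusted p values of the 7 ran from 0.0231 to 0.0477 in edgeR. With the replicate number as a block 0 ASVs passed (lowest edgeR adjusted p = 0.571). Under each of TMM, total-read and poscounts scaling 1 ASV passed. Without libraries 34 to 38, 5 of the 7 were still among the 1001 ASVs tested (not ASV288 and ASV514) and 0 passed. Interaction folds (log2) were then 14.34 against 14.31 for ASV278, -8.99 against -8.74 for ASV856, -9.73 against -9.42 for ASV979, -9.36 against -10.31 for ASV622 and 6.66 against 11.44 for ASV397.

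Exchange of bacteria between cohoused animals could bring the groups closer together, but the distances given here cannot test it. Separately kept old and young libraries lay 0.597 apart, between the means within young (0.646) and within old libraries (0.572). No age gap was thus seen that exchange could close. The labels name no cages, so pairs of cage-mates could not be singled out. Cohoused young libraries lay at a mean Bray-Curtis dissimilarity of 0.572 ± 0.131 (SD, n = 10) from the old libraries, and young libraries at 0.597 ± 0.114 (permutation p = 0.647). Cohoused old libraries lay at 0.644 ± 0.114 from the young libraries, and old libraries at 0.597 ± 0.102 (permutation p = 0.319). Old and young libraries were on average 0.625 apart when cohoused and 0.597 apart when kept separately (permutation of housing within age, p = 0.674). At genus level this last difference turned from 0.0280 to -0.00647. Across the pairs not yet named, cohoused young and old libraries differed with 2.83% of the variation (PERMANOVA p = 0.862) and cohoused old and young libraries with 2.66% (p = 0.826).

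Transfer of single ASVs was to be measured as the share of reads in ASVs called between old and young libraries on a part of the libraries kept apart from the test. No ASV was called on that part by edgeR in either direction, so no share was computed.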

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

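The tests of explanations and the counts of other splits given here were chosen after the results were seen, and the 2 rules that pick single libraries and interaction results were set in advance.

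Single libraries far from the other 9 of their group were sought with Dixon's test in 100 groups of values, and 21 values stood out. Chance alone picks about 1 in 20 groups of normal values. Many of these percents are skewed with medians near 0, and some share reads, so the 21 cannot be read as an excess. Of the Shannon values, old 9 had 2.87 and cohoused young 10 had 2.97. Parabacteroides goldsteinii held 0.754% in young 9, 4.47% in old 9 and 1.96% in cohoused young 10. Turicibacter held 12.9% in young 9 and 12.2% in cohoused young 10. Proteobacteria held 6.95% in cohoused old 9, as did the proteobacterial opportunists (6.95%), and Erysipelotrichales held 27.5% in cohoused young 10. These 10 values come from libraries 34, 35, 36 and 38. The other 11 came from elsewhere. Cohoused old 4 had 1.48% Deferribacterota and 1.498% mucin users, which share Mucispirillum. Cohoused old 5 had 45.5% Lactobacillus and 45.5% lactic acid bacteria. Sulfidogenic bacteria held 0.163% in young 8, segmented filamentous bacteria 2.44% in young 2 and 1.14% in old 3, Bacteroides 6.40% in old 1 and Muribaculaceae 12.7% in cohoused young 7. Staphylococcus, the only reagent or skin genus found, held 0.0412% in young 10 and 0.390% in old 10.

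Libraries 34 to 38 have totals of 44298 to 101944 reads, and 4 of the 5 lie inside the range of the other 35, 53096 to 135690, which argues against low depth as the cause. Reagent and skin genera held at most 0.00486% of their reads, which argues against contamination by them. Their numbers form 1 run, for which 5 random numbers out of 40 have a chance of 5.47e-05. Something shared that follows the library number, such as a cage, a handling day or a source of mice, may therefore be involved, and the labels give none of these. With labels matched by number the run carries all 4 of them, so age and cohousing do not account for it if that match is right.

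That no difference between the 4 groups was detected has more than 1 open reading. Leaving out the 5 far libraries gave 5.72% of variation for the groups, below the 13.1% at the 95th percentile of permuted labels, which argues against these libraries hiding a difference. Permuting within blocks of consecutive numbers gave p = 0.965, so no group difference emerged there either. A wrong match between columns and samples and true likeness of the 4 groups both predict a share of variation within the range of permuted labels, and 4.52% against 12.4% was seen. A true difference too small to detect with 10 libraries per group would predict the same. These readings cannot be told apart from these values, and the likeness of consecutive numbers holds for the columns whatever their labels.

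The interaction of age and cohousing passed for 7 ASVs in edgeR (adjusted p from 0.0231 to 0.0477). ASV278, ASV288, ASV397 and ASV514 had interaction folds above 0 (ASV288 turned to -1.88 in DESeq2), and ASV622, ASV856 and ASV979 below 0. Chance cannot be excluded: 47 of 100 splits of the libraries called at least 7 ASVs, the real one included, with up to 87 in another split. For old against young, with 2 ASVs called, 29 of 100 splits called as many, with up to 100 in another split, so chance cannot be excluded there. For the other ASV contrasts 0 passed, so 100 of 100 splits necessarily called as many and the count says nothing about chance. Other splits called up to 135 for cohoused young against young, 94 for cohoused old against old and 61 between the cohoused groups. The same holds at genus level, where 0 passed, 100 of 100 splits called as many and other splits called up to 3 for old against young, 3 for cohoused young against young, 7 for cohoused old against old, 4 between the cohoused groups and 11 for the interaction. The median of the other splits was 6 for the ASV interaction and 0 for every other contrast, so the high numbers are not typical of the splits. The single splits with 100 and 87 ASVs may reflect a structure of the libraries other than the labels. Which libraries they group was not examined.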

How the results depend on the processing

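Leaving out libraries 34 to 38, blocks of consecutive numbers and the log10 scale for fixed taxa were chosen after the data were seen.

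All 35 PERMANOVA alternatives stayed above p = 0.05 (0.287 to 0.992). In 6 of 6 alternatives 0 phylum or list shares passed, and 43 of 44 for diversity and distances kept their direction, with none passing. The exception was the between-age distance, -0.00647 at genus level (permutation p = 0.880). Counts of taxa stayed within 1.5 times in 71 of 98 alternatives, but most of these set 0 against 0 and say little about stability. Where the main fit had calls, few alternatives kept the count. For old against young only the filter of 10 reads in 10 libraries did, with 2 ASVs. For the interaction only DESeq2 did, with 9 ASVs against 7, of which 2 were shared. DESeq2 called 1 genus for old against young, 1 for cohoused old against old and 1 for the interaction, where edgeR called 0. It called 14 ASVs for old against young, 6 for cohoused young against young, 6 for cohoused old against old and 4 between the cohoused groups. Without the low-count filter, edgeR called 438, 425, 461 and 102 ASVs in these contrasts and 329 for the interaction. For old against young 0 ASVs passed under TMM, total reads, poscounts, limma, the fit of these groups alone and without libraries 34 to 38. For cohoused old against old the fit of these groups alone called 15. For the interaction 1 passed under each of TMM, total reads and poscounts, and 0 under limma and without libraries 34 to 38, where 5 of the 7 were still tested. With 10 reads in 10 libraries 0 passed because the filter removed all 7. Otherwise the cause was not tested.

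The replicate number as a block left 0 ASVs for old against young and 0 for the interaction, and turned the interaction of ASV288 to -0.26 (log2); DESeq2 gave -1.88. Same-numbered libraries deviated with a mean correlation of 0.211 over 60 pairs, 41 of them above 0.1, against -0.00866 over 540 others. Every pair of numbers 2, 3 and 10 exceeded 0.1, and 9 of 40 libraries correlated best with their own number. Same-numbered libraries were thus more alike on average, but not in every pair. The block was left out of the reported fit, so that fit does not account for this likeness. Within each group the replicate numbers rise with the library numbers. This likeness and that of consecutive library numbers therefore cannot be told apart. With the block, Anaeroplasma over its list alone had an edgeR adjusted p of 0.200 (cohoused old against old) and 0.498 (cohoused groups).

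Among 56 alternatives for the fixed taxa 15 reversed, and none passed in either setting. Without libraries 34 to 38 the differences in percentage points were -0.00769 (old against young) and -0.00788 (cohoused young against young) for Parabacteroides goldsteinii. They were 1.20 (cohoused young against young) and -0.0775 (cohoused groups) for Lactobacillus, and -0.0766 (cohoused groups) for Turicibacter. For the cohoused groups they were 0.375 for Bacteroides and 0.194 for Alistipes, and for cohoused old against old 0.200 for Alistipes. On the log10 scale, old against young gave 0.125 for Alistipes and 0.0549 for Lactobacillus. Cohoused young against young gave 0.0520 for Alistipes, 0.108 for Lactobacillus and 0.128 for Turicibacter. Cohoused old against old gave -0.182 for Bacteroides, and the cohoused groups -0.0286 for Lactobacillus. Turicibacter, cohoused old against old, turned to a log2 fold change of 0.15 under TMM. The cause was not tested.

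No library fell under 1000 reads, so keeping such libraries changed nothing, and the transfer shares had no value under either split of the libraries. Depth limits rare taxa: 0 reads in a library allow up to 0.00221% to 0.00677%.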

Other observations

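The comparison of consecutive library numbers and the sets of libraries described here were chosen after the data were seen.

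Libraries 34 to 38 held a distinct community, whatever their label. Their dissimilarity was 0.224 to 0.388 among themselves and 0.727 to 0.981 to the other 35. Bacteroidota held 15.1% to 27.7% of their reads (24.1% to 58.2% in the others), Romboutsia 2.29% to 7.49% (0% to 4.62%) and Parasutterella 3.66% to 6.95% (0.159% to 3.34%). Alistipes held at most 0.00762% (0.102% to 6.71%) and Odoribacter, a producer of short-chain fatty acids, at most 0.00544% (0.527% to 4.01%). Rikenella and segmented filamentous bacteria had 0 reads in all 5 (0% to 1.30% and 0% to 2.44% in the others). Libraries 2, 10, 20, 22 and 23 also had 0 reads of segmented filamentous bacteria and at most 0.00363% Rikenella. Shannon diversity was 2.87 to 3.38 (3.54 to 5.44). Libraries 39 and 40 (young 10 and old 10) shared the high Turicibacter, 3.27% and 14.9%, and Romboutsia, 2.39% and 4.62%.

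Libraries 2, 10, 20, 22 and 23 (cohoused young 1, young 4, cohoused old 4, young 8 and cohoused old 5) formed another set. They were picked by their near lack of ASV1 of Prevotellaceae, so their low ASV1 share follows from that choice. ASV1 held 0.00643% to 0.0186% of their reads. In the remaining 30, left after libraries 34 to 38 were also set aside, ASV1 held 1.58% to 15.6%. Segmented filamentous bacteria had 0 reads in all 5 and held 0.0398% to 2.44% in the remaining 30. Patescibacteria had 0 reads in all 5 and were found in 26 of the remaining 30. Dubosiella held 4.17% to 15.1% and Faecalibaculum 3.33% to 12.2%, ranges that overlap those of the remaining 30, 0% to 6.97% and 0.00430% to 5.35%. No old library is among these 5, and the means of Dubosiella and Faecalibaculum in the other 3 groups include them. The near lack of ASV1 is not particular to this set, because ASV1 held 0.00392% to 0.0185% in libraries 34 to 38. Libraries 34 to 38 also had 0 reads of Patescibacteria and of segmented filamentous bacteria. Faecalibaculum, in contrast, held at most 0.00218% in libraries 34 to 38.

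Neighbours in the order of library numbers stayed alike without libraries 34 to 38, where 33 and 39 counted as neighbours. Their mean dissimilarity was 0.493 over 34 pairs against 0.533 in random orders (1-sided permutation p = 0.0106).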
